A study of Mus musculus with 16 samples.

How the data were processed

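The glands were profiled on dual-colour Agilent oligonucleotide arrays of mouse genes, 16 arrays in 8 dye-swapped pairs. Per the labels, each array carried the RNA of 1 estradiol pool in one dye and of a day 7 placebo pool in the other, with 4 to 5 mice per pool. An experiment is the set of pools that share a placebo label: WK1-placebo (replicate 1 of days 7, 14 and 28) or d7 placebo (replicate 2 of these days, and days 2 and 5). The labels give no time-matched placebo except for day 7. The numbers of the replicates were checked for pairing: deviations of same-numbered pools from their day means correlated across genes with r of 0.453 to 0.604 between days, so the experiment was also tried as a block.

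The authors scanned the arrays and read them with Agilent Feature Extraction. The series and sample notes name versions 7.5 and 8.1 with default parameters, and per the file headers the version was 7.5.1 for the arrays with WK1-placebo and 8.1.1.1 for the others. The deposited scanner files hold spot intensity values, the mean pixel brightness in Cy5 and Cy3 and the median of the local background, with no normalization. They also hold the log10 ratio of Cy5 over Cy3, which per the file headers the software made after background subtraction with spatial detrending and a linear and lowess dye normalization. The 0 and 1 marks of the deposited files for spots well above background, saturated spots and outlier spots were used as other values with no scale. The deposited value table holds the same log10 ratio (r of 1 in size, differences of at most 0.005), with its sign turned on the arrays that carried estradiol in Cy3. Its column medians lay between -0.0013 and 0.00196.

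Each array has 22393 spots, of which 21318 are for genes and 1075 are controls, and the gene spots are of 20868 probes. Names came from the accession of 13969 probes, a current symbol of 2385 and an older symbol of 2255, and 2259 probes kept the name in the file, which gave 19481 gene names. Outlier spots, 23 to 548 per array, were left out, and 0 to 28 spots per array and channel were saturated. Probes were kept where either channel was well above background on both arrays of at least 1 pool, which kept 20421 probes and left out 447. Where a gene had several probes (1196 genes), the one with the highest mean signal over all arrays stood for it. Of these genes 500 had a probe that passed over days 7, 14 and 28, and 9 had probes that passed in opposite directions. In all 19108 genes were tested, of which 42 lacked a pool and 4 lacked a day through outlier spots.

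Signals were background corrected by normexp with an offset of 50 and normalized by loess within each array, in R 4.3.3 with limma 3.58.1. Log2 ratios were turned so that estradiol is over placebo, and the 2 arrays of a dye swap (r across genes 0.662 to 0.869) were averaged, so that 1 RNA pool is 1 value. Limma was fitted to the 8 values per gene with 1 coefficient per day and its moderated variance (3 residual and 2.24 prior degrees of freedom). The 8 contrasts were the 5 days, the mean over days 7, 14 and 28, day 28 minus day 7, and the mean of days 2 and 5 minus the mean of days 7, 14 and 28. Adjusted p values are by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05, and tests are 2-sided. Days 2 and 5 have 1 pool and take their spread from the other days. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

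The 22 gene lists, with 567 entries, held 549 measured genes, 16 entries were not on the arrays under a known name, 2 were other names of a listed gene, and 7 measured genes stood in more than 1 list. The lists were: estrogen receptor target and hormone signalling, DNA replication, mitosis, luminal epithelial, basal and myoepithelial, milk protein and secretory, adipocyte, lipid synthesis, brown adipocyte and thermogenic, fatty acid oxidation and mitochondrial, fibrillar collagen and matrix, matrix remodelling, macrophage and myeloid, lymphocyte and lymph node, antigen presentation and interferon, endothelial, skeletal muscle, nerve and Schwann cell, red blood cell, immediate early and stress, growth factor and branching, and secretory pathway and protein folding genes. Camera with a preset correlation of 0.01 asked whether a list moved relative to the other genes, and camera with an estimated correlation and fry (directional p) were run beside it, each adjusted over the 22 lists. Member counts are given over all genes and adjusted over the list alone. For days 7, 14 and 28 the genes named are those with a symbol that passed with one sign on all 4 arrays, the 10 highest and the 10 lowest. For days 2 and 5 they are the 5 highest and 5 lowest with one sign on both arrays, and for the contrasts between days the 5 highest and 5 lowest that passed, filled up with the largest ratios at an unadjusted p under 0.05. Up to 4 members of each list with the smallest p over days 7, 14 and 28 and 22 fixed genes were added. The comparisons, lists, alternatives and naming rules were chosen before the data were examined, except the fits of each experiment alone.

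The fit was tested on simulated data with the same 8 pools and 19108 genes, with 50 genes changed at each size. At log2 changes of 0.5, 1, 2 and 3, the share recovered was 80, 86, 98 and 100% for day 7 with 6 false calls, and 56, 80, 98 and 98% for day 2 with 12. It was 88, 98, 100 and 100% for the mean over days 7, 14 and 28 with 8 false calls, and 58, 80, 94 and 98% for day 28 minus day 7 with 11, where data with no change gave 0 calls. The other days and the contrast of early with later days were not simulated. Camera called the raised list and 0 of 20 unchanged ones. This does not cover lists of correlated genes (estimated at up to 0.865 here). Nor do the false calls cover correlated pools. The alternatives tried were: no background correction; median centring; the deposited log ratio and value table; no filter and a strict filter (16424 probes); every probe on its own; the experiment as a fixed or random block; 1 dye orientation at a time; a variance prior with a trend; each replicate of days 7, 14 and 28 left out; and each experiment alone.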

Results

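Gene expression was measured in the #4 mammary gland, an abdominal fat pad with its epithelial ducts, of ovariectomised mice given estradiol or placebo. Estradiol glands were taken at days 2, 5, 7, 14 and 28. RNA of 4 to 5 mice was pooled per group, and each estradiol pool was hybridised against a day 7 placebo pool on 2 dye-swapped arrays. The 16 arrays thus gave 8 ratios of estradiol over placebo, and n counts these ratios: 2 at each of days 7, 14 and 28, and 1 at each of days 2 and 5. Replicate 1 of days 7, 14 and 28 was hybridised with the placebo labelled WK1-placebo, and the other 5 pools with the one labelled d7 placebo. The day 7 comparison alone was matched in time. For the other days the series design gives the day 7 placebo as the control because the placebo fat pad becomes fatter by days 14 and 28.

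On the 6 arrays with WK1-placebo, 84.1 to 95.2% of gene spots were well above background, with median spot signals of 116 to 229. On the 10 arrays with d7 placebo these were 95.5 to 98.3% and 309 to 596. The number of arrays limits the precision. Across 19066 genes, which are not independent replicates, the 2 ratios of a day correlated with r of 0.724 at day 7, 0.823 at day 14 and 0.770 at day 28. Values below are log2 ratios with the standard error (SE) of the limma fit after ±, and a gene rose or fell where its adjusted p was under 0.05. Each gene named as risen or fallen at days 7, 14 or 28 had that direction in both pools. Lists are counted by their measured genes, and brackets after those that rose, fell or did not pass give how many rose and fell when adjusted over the list alone. Leaving out a pool also lowered the residual degrees of freedom from 3 to 2.

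The day 7 comparison asks which genes estradiol changed against placebo of the same day (n = 2). Spon1, which encodes an extracellular matrix protein, rose 12.1-fold (log2 3.60 ± 0.068, adjusted p = 0.000295), with 3.55 and 3.65 in the 2 pools. Gas6, a ligand of the Axl family of receptor kinases, rose 11.9-fold (log2 3.58 ± 0.12, adjusted p = 0.00142), and the chemokine gene Ccl8 rose 11.3-fold (log2 3.50 ± 0.13, adjusted p = 0.00142). Krt8, a keratin of luminal epithelium, rose 6.20-fold (log2 2.63 ± 0.057, adjusted p = 0.000295), with 2.54 and 2.73 in the 2 pools. Areg, which encodes amphiregulin, a ligand of the EGF receptor, rose 5.99-fold (log2 2.58 ± 0.25, adjusted p = 0.00619). Mmd2 (log2 3.29 ± 0.11), Cilp (log2 2.92 ± 0.21), Krt19 (log2 2.70 ± 0.30), Lrg1 (log2 2.48 ± 0.12) and Plod2 (log2 2.46 ± 0.22) completed the 10 genes that rose most.

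Genes of brown fat and lipid metabolism were among those that fell most at day 7 (n = 2). Ucp1, the uncoupling protein of brown fat, was 6.62-fold lower (log2 -2.73 ± 0.56, adjusted p = 0.0448), with -3.99 and -1.46 in the 2 pools. Rbp4, a retinol carrier, was 5.34-fold lower (log2 -2.42 ± 0.15, adjusted p = 0.00245), and Cidea, a lipid droplet protein, was 5.20-fold lower (log2 -2.38 ± 0.25, adjusted p = 0.00806). Insig1 was 3.96-fold lower (log2 -1.99 ± 0.27, adjusted p = 0.0148). Ces1f (log2 -1.81 ± 0.070), Fabp3 (log2 -1.70 ± 0.24), Elovl6 (log2 -1.67 ± 0.29), Cox7a1 (log2 -1.67 ± 0.21), Orm1 (log2 -1.86 ± 0.15) and Orm2 (log2 -1.62 ± 0.16) also fell. Orm1, Orm2 and Ces1f belong to families with near-identical members, so a probe may not separate them. Calls lost with 1 pool left out were those of Cidea without day 7 replicate 1 (adjusted p = 0.0730), Fabp3 without it (adjusted p = 0.0989), and Insig1 without day 7 replicate 1 (adjusted p = 0.0732) or 2 (adjusted p = 0.0988). Elovl6 was lost without day 7 replicate 1 (adjusted p = 0.192) or 2 (adjusted p = 0.0698) and without either day 28 pool (adjusted p = 0.0602). Ucp1 was lost without either day 14 pool (adjusted p = 0.0963) or either day 28 pool (adjusted p = 0.0960). It was also lost with no background correction (adjusted p = 0.0510), from the deposited log ratio (adjusted p = 0.0541) and from arrays with estradiol in Cy5 (adjusted p = 0.167).

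By group at day 7, of 28 macrophage and myeloid genes, 21 rose, 0 fell and 7 did not pass (23 and 0 within the list). They include the mannose receptor Mrc1 (log2 1.59 ± 0.075, adjusted p = 0.00165) and the scavenger receptor Cd163 (log2 1.39 ± 0.052, adjusted p = 0.00142), which rose. Of 29 fibrillar collagen and matrix genes, 16 rose, 1 fell and 12 did not pass (19 and 2 within the list). Lum (log2 1.07 ± 0.058) and Fbn1 (log2 0.98 ± 0.062) rose. Of 30 luminal epithelial genes, 10 rose, 0 fell and 20 did not pass (17 and 0 within the list). Of 28 lymphocyte and lymph node genes, 0 rose, 17 fell and 11 did not pass (0 and 24 within the list). Cd5 (log2 -0.47 ± 0.049) and Cd2 (log2 -0.60 ± 0.055) fell. Of 32 fatty acid oxidation and mitochondrial genes, 1 rose, 20 fell and 11 did not pass (1 and 30 within the list). Of 14 brown adipocyte and thermogenic genes, 1 rose, 9 fell and 4 did not pass (1 and 11 within the list). Of 22 skeletal muscle genes, 0 rose, 0 fell and 22 did not pass (0 and 0 within the list). Their median was -2.56 in replicate 1 and 0.019 in replicate 2. In the same pools the median was -1.19 and -0.58 for the brown adipocyte and thermogenic genes, and -0.70 and -0.40 for the fatty acid oxidation and mitochondrial genes. Of 29 lipid synthesis genes, 0 rose, 11 fell and 18 did not pass (0 and 18 within the list). Of 28 adipocyte genes, 1 rose, 9 fell and 18 did not pass (2 and 12 within the list). Of 24 immediate early and stress genes, 7 rose, 0 fell and 17 did not pass (9 and 2 within the list). Egr2 (log2 2.43 ± 0.12) and Jun (log2 0.60 ± 0.037) rose.

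In all, 1860 of 19108 genes passed at day 7, 1112 higher and 748 lower, and 224 of them differed at least 2-fold. The count was 3313 with the experiment as a block, 391 without day 7 replicate 1 (273 higher, 118 lower) and 810 without replicate 2 (359 higher, 451 lower). Camera moved 12 lists up and 7 down of 22, and 0 with an estimated correlation, where the smallest adjusted p was 0.264. Among these calls, those of the estrogen receptor target and hormone signalling genes (adjusted p = 0.131), DNA replication genes (adjusted p = 0.0628), basal and myoepithelial genes (adjusted p = 0.229), milk protein and secretory genes (adjusted p = 0.0730) and endothelial genes (adjusted p = 0.0562) were lost without day 7 replicate 2. Those of the skeletal muscle genes (adjusted p = 0.867) and red blood cell genes (adjusted p = 0.128) were lost without day 7 replicate 1. From arrays with estradiol in Cy5 those of the matrix remodelling genes (adjusted p = 0.0915) and immediate early and stress genes (adjusted p = 0.0824) were lost.

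At day 14 (n = 2), set against the day 7 placebo, Cilp, a cartilage matrix protein, rose 13.6-fold (log2 3.76 ± 0.21, adjusted p = 0.00123), with 3.77 and 3.76 in the 2 pools. Spon1 rose 10.7-fold (log2 3.42 ± 0.068, adjusted p = 0.000277). Ccl8 (log2 3.46 ± 0.13), Mmd2 (log2 2.95 ± 0.11), Ccn5 (log2 2.77 ± 0.17), Krt19 (log2 2.67 ± 0.30), Krt8 (log2 2.67 ± 0.057), Akr1c14 (log2 2.64 ± 0.30), Plod2 (log2 2.40 ± 0.22) and Lrrc17 (log2 2.30 ± 0.094) rose as well. Cox7a1, a subunit of cytochrome oxidase in muscle and brown fat, was 5.29-fold lower (log2 -2.40 ± 0.21, adjusted p = 0.00305), with -2.51 and -2.30 in the 2 pools. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 3.52-fold lower (log2 -1.81 ± 0.20, adjusted p = 0.00609), and Ppara, a nuclear receptor that drives fatty acid oxidation, was 2.95-fold lower (log2 -1.56 ± 0.20, adjusted p = 0.00898). Insig1 (log2 -2.24 ± 0.27), Rbp4 (log2 -2.13 ± 0.15), Ces1f (log2 -2.10 ± 0.070), Fabp3 (log2 -1.77 ± 0.24), Rasl12 (log2 -1.66 ± 0.12), Aatk (log2 -1.52 ± 0.055) and Slc2a5 (log2 -1.49 ± 0.31) fell too. Without day 14 replicate 1 the calls were lost of Cox7a1 (adjusted p = 0.0551), Insig1 (0.0736), Plod2 (0.0580) and Akr1c14 (0.0854). The same held for Fabp3 (adjusted p = 0.121), Krt19 (0.0618), Ppara (0.0714) and Slc2a5 (0.283). Without day 14 replicate 2 they were lost of Akr1c14 (adjusted p = 0.0568), Fabp3 (0.0510), Krt19 (0.0628), Ppara (0.0845) and Slc2a5 (0.0801). Slc2a5 was also lost without either day 28 pool (adjusted p = 0.0597) and from arrays with estradiol in Cy5 (adjusted p = 0.0560).

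By group at day 14, of 29 fibrillar collagen and matrix genes, 21 rose, 1 fell and 7 did not pass (21 and 2 within the list). Lum (log2 1.57 ± 0.058), Fbn1 (log2 1.67 ± 0.062) and Loxl1 (log2 1.52 ± 0.062), a lysyl oxidase that cross-links elastin, rose. Of 26 matrix remodelling genes, 10 rose, 2 fell and 14 did not pass (12 and 2 within the list). The matrix metalloproteinases Mmp2 (log2 1.41 ± 0.10) and Mmp14 (log2 1.34 ± 0.088) rose. Of 28 macrophage and myeloid genes, 23 rose, 0 fell and 5 did not pass (23 and 0 within the list). Of 32 fatty acid oxidation and mitochondrial genes, 1 rose, 29 fell and 2 did not pass (1 and 30 within the list). Idh3a (log2 -1.26 ± 0.059), an enzyme of the citric acid cycle, fell. Of 14 brown adipocyte and thermogenic genes, 1 rose, 12 fell and 1 did not pass (1 and 13 within the list). Skeletal muscle genes had medians of -1.44 and -0.057 in replicates 1 and 2, where the thermogenic genes had -1.49 and -1.19 and the fatty acid oxidation genes -0.73 and -0.66. Of 28 lymphocyte and lymph node genes, 0 rose, 19 fell and 9 did not pass (0 and 21 within the list). Of 32 mitosis genes, 6 rose, 0 fell and 26 did not pass (14 and 0 within the list). Of 30 luminal epithelial genes, 9 rose, 0 fell and 21 did not pass (11 and 0 within the list). Of 24 secretory pathway and protein folding genes, 7 rose, 0 fell and 17 did not pass (17 and 0 within the list).

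In all, 2762 genes passed at day 14, 1538 higher and 1224 lower. The count was 4250 with the experiment as a block, 532 without day 14 replicate 1 (385 higher, 147 lower) and 1072 without replicate 2 (697 higher, 375 lower). Camera moved 9 lists up and 7 down, and 0 with an estimated correlation (smallest adjusted p = 0.246). Among these calls, those of the antigen presentation and interferon genes (adjusted p = 0.324) and skeletal muscle genes (adjusted p = 0.832) were lost without day 14 replicate 1, and that of the basal and myoepithelial genes (adjusted p = 0.139) without day 14 replicate 2. That of the milk protein and secretory genes was lost with median centring (adjusted p = 0.0568), and the block newly called the DNA replication genes (adjusted p = 0.0380).

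At day 28 (n = 2), against the day 7 placebo, Krt19 rose 11.8-fold (log2 3.56 ± 0.30, adjusted p = 0.00475) and Krt8 11.2-fold (log2 3.48 ± 0.057, adjusted p = 0.000204), with 3.55 and 3.42 in the pools of Krt8. Both are keratins of the luminal epithelium, as is Krt18, which rose 7.97-fold (log2 2.99 ± 0.11, adjusted p = 0.00123). Spon1 rose 8.90-fold (log2 3.15 ± 0.068, adjusted p = 0.000440) and Areg 8.69-fold (log2 3.12 ± 0.25, adjusted p = 0.00433). Pla1a (log2 2.57 ± 0.13), Ccl8 (log2 2.52 ± 0.13), Wfdc18 (log2 2.47 ± 0.20), Mup5 (log2 2.57 ± 0.16) and Mup4 (log2 2.47 ± 0.33) also rose, and the Mup genes are near-identical, so a probe may not separate them. Cox8b, a cytochrome oxidase subunit of muscle and brown fat, was 3.59-fold lower (log2 -1.84 ± 0.18, adjusted p = 0.00647), with -1.75 and -1.94 in the 2 pools. Acly was 2.65-fold lower (log2 -1.41 ± 0.26, adjusted p = 0.0338), and Acaa2 was 2.40-fold lower (log2 -1.26 ± 0.10, adjusted p = 0.00464). Slc2a5 (log2 -1.61 ± 0.31), Rasl12 (log2 -1.49 ± 0.12), Ppara (log2 -1.41 ± 0.20), Fabp3 (log2 -1.32 ± 0.24), Acot11 (log2 -1.28 ± 0.24), Tmem182 (log2 -1.25 ± 0.14) and Coq8a (log2 -1.25 ± 0.13) fell too. Without day 28 replicate 2 the calls were lost of Krt19 (adjusted p = 0.0638), Areg (0.0553), Wfdc18 (0.0563), Mup4 (0.0751), Cox8b (0.0895) and Acly (0.178). The same held for Acaa2 (adjusted p = 0.0598), Acot11 (0.188), Coq8a (0.0762), Fabp3 (0.147), Ppara (0.135), Slc2a5 (0.273) and Tmem182 (0.0988). Without day 28 replicate 1 they were lost of Mup4 (adjusted p = 0.0910), Cox8b (0.0554), Acaa2 (0.0502), Acot11 (0.194), Fabp3 (0.195) and Slc2a5 (0.111). Without either day 14 pool they were lost of Acly (adjusted p = 0.0757), Fabp3 (0.0557) and Slc2a5 (0.0533). From the deposited log ratio the calls of Acot11 (adjusted p = 0.0575) and Fabp3 (adjusted p = 0.0587) were lost, and from arrays with estradiol in Cy5 those of Acot11 (adjusted p = 0.0635) and Slc2a5 (adjusted p = 0.0572).

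By group at day 28, of 30 luminal epithelial genes, 18 rose, 0 fell and 12 did not pass (25 and 0 within the list). Krt7 (log2 2.25 ± 0.084), a keratin, rose. Of 22 basal and myoepithelial genes, 7 rose, 0 fell and 15 did not pass (12 and 2 within the list), and the keratin gene Krt15 (log2 2.22 ± 0.12) was among the risen. Of 24 estrogen receptor target and hormone signalling genes, 6 rose, 0 fell and 18 did not pass (8 and 0 within the list). Of 28 macrophage and myeloid genes, 18 rose, 0 fell and 10 did not pass (22 and 0 within the list). Of 28 lymphocyte and lymph node genes, 1 rose, 22 fell and 5 did not pass (1 and 24 within the list). Of 32 fatty acid oxidation and mitochondrial genes, 1 rose, 24 fell and 7 did not pass (1 and 30 within the list). Of 14 brown adipocyte and thermogenic genes, 1 rose, 10 fell and 3 did not pass (1 and 11 within the list). Ucp1 (log2 -3.88 ± 0.56), lost without either day 28 pool (highest adjusted p = 0.166), and Cidea (log2 -2.83 ± 0.25) fell. Skeletal muscle genes had medians of -1.34 and -0.39 in replicates 1 and 2, where the thermogenic genes had -1.12 and -0.91 and the fatty acid oxidation genes -0.55 and -0.62. Of 22 skeletal muscle genes, 0 rose, 1 fell and 21 did not pass (0 and 0 within the list). The fallen gene was Casq1 (log2 -0.82 ± 0.17, adjusted p = 0.0447), lost without each pool of days 14 and 28 (highest adjusted p = 0.257). Of 29 fibrillar collagen and matrix genes, 12 rose, 1 fell and 16 did not pass (13 and 2 within the list). Of 24 milk protein and secretory genes, 4 rose, 0 fell and 20 did not pass (7 and 1 within the list), and Csn3, a casein, was 2.64-fold higher (log2 1.40 ± 0.089, adjusted p = 0.00274). From arrays with estradiol in Cy5 the calls of Ucp1 (adjusted p = 0.158) and Casq1 (adjusted p = 0.0873) were lost, and that of Casq1 also from the deposited log ratio (adjusted p = 0.142).

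In all, 1843 genes passed at day 28, 1045 higher and 798 lower. The count was 3412 with the experiment as a block, 553 without day 28 replicate 1 (403 higher, 150 lower) and 189 without replicate 2 (137 higher, 52 lower). Camera moved 10 lists up and 7 down, and 0 with an estimated correlation (smallest adjusted p = 0.272). Among these calls, those of the DNA replication genes (adjusted p = 0.911) and adipocyte genes (adjusted p = 0.334) were lost without day 28 replicate 2 and without each pool of days 7 and 14 (adjusted p = 0.0521 to 0.0614). That of the skeletal muscle genes (adjusted p = 0.224) was lost without day 28 replicate 1, and the block newly called the growth factor and branching genes (adjusted p = 0.0475).

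Days 2 and 5 had 1 pool each (n = 1), so the spread of their ratios was assumed to be that of the replicated days. At day 2 Gas6 was already 10.4-fold higher (log2 3.38 ± 0.17, adjusted p = 0.0122), Mmd2 10.2-fold higher (log2 3.36 ± 0.16, adjusted p = 0.0122) and Spon1 8.48-fold higher (log2 3.08 ± 0.096, adjusted p = 0.00605). Lrg1, a secreted glycoprotein, rose 6.54-fold (log2 2.71 ± 0.16, adjusted p = 0.0153), and Mt2, a metallothionein whose probe may also read its close relatives, rose 5.79-fold (log2 2.54 ± 0.34, adjusted p = 0.0473). Ptger3, a prostaglandin E receptor, was 4.17-fold lower (log2 -2.06 ± 0.21, adjusted p = 0.0309), and the adipocyte hormone gene Retn was 3.17-fold lower (log2 -1.67 ± 0.11, adjusted p = 0.0179). Ces1f (log2 -1.73 ± 0.099), Rbp4 (log2 -1.68 ± 0.21) and Dgat2, which makes triglyceride (log2 -1.36 ± 0.11), fell too. At day 5 Ccl8 was 10.9-fold higher (log2 3.44 ± 0.18, adjusted p = 0.00897), and Mmd2 (log2 3.48 ± 0.16), Spon1 (log2 3.41 ± 0.096), Gas6 (log2 3.38 ± 0.17) and Cilp (log2 2.77 ± 0.29) rose as well. Rbp4 (log2 -2.54 ± 0.21), Ptger3 (log2 -2.26 ± 0.21), Cyp2f2 (log2 -1.94 ± 0.23), Ces1f (log2 -1.92 ± 0.099) and Retn (log2 -1.83 ± 0.11) fell at day 5. Leaving out any of the 6 pools of days 7, 14 and 28 ended the day 2 calls of Ptger3 (adjusted p = 0.0521 to 0.0665) and Rbp4 (adjusted p = 0.0602 to 0.0829). The day 2 calls of Mt2 (adjusted p = 0.108) and Dgat2 (adjusted p = 0.0521) and the day 5 call of Cilp (adjusted p = 0.0694) ended without either day 14 pool. Those of Mt2 at day 2 (adjusted p = 0.101), Cilp at day 5 (adjusted p = 0.0547) and Cyp2f2 at day 5 (adjusted p = 0.0833) ended without either day 28 pool, and Cyp2f2 also without either day 7 pool (adjusted p = 0.0540). From the deposited log ratio the calls were lost of Mt2 (adjusted p = 0.0633), Ptger3 (0.0502) and Rbp4 (0.0652) at day 2 and of Cyp2f2 at day 5 (0.110). The same 4 calls were lost from arrays with estradiol in Cy5 (adjusted p = 0.128, 0.0730, 0.0701 and 0.0532), and those of Mt2 (adjusted p = 0.0567) and Rbp4 (adjusted p = 0.0508) with no background correction.

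By group, of 32 mitosis genes, 14 rose, 0 fell and 18 did not pass (31 and 0 within the list) at day 2. Top2a, a topoisomerase of dividing cells, was 1.77-fold higher (log2 0.82 ± 0.076, adjusted p = 0.0272) and the proliferation marker Mki67 1.66-fold higher (log2 0.73 ± 0.10, adjusted p = 0.0485). Top2a was lost without each pool of days 7 and 14 (highest adjusted p = 0.0677), and Mki67 without each of the 6 pools of days 7, 14 and 28 (highest adjusted p = 0.0879). Of 29 DNA replication genes, 5 rose, 0 fell and 24 did not pass (19 and 0 within the list) at day 2. Of 28 macrophage and myeloid genes, 11 rose, 0 fell and 17 did not pass (16 and 1 within the list) at day 2, and 14 rose, 0 fell and 14 did not pass at day 5 (21 and 0 within the list). The chemokine gene Ccl6 was 3.85-fold higher (log2 1.94 ± 0.075, adjusted p = 0.0138) at day 2. Of 30 luminal epithelial genes, 3 rose, 0 fell and 27 did not pass (5 and 0 within the list) at day 2. Krt8 (log2 1.46 ± 0.080) rose. From arrays with estradiol in Cy5 the day 2 calls were lost of Top2a (adjusted p = 0.114), Mki67 (adjusted p = 0.336) and Krt8 (adjusted p = 0.0694). Mki67 was also lost from the deposited log ratio (adjusted p = 0.0806), with no background correction (adjusted p = 0.0566) and with every probe on its own (adjusted p = 0.0510). Of 32 mitosis genes, 1 rose, 0 fell and 31 did not pass (25 and 1 within the list) at day 5. Of 32 fatty acid oxidation and mitochondrial genes, 0 rose, 2 fell and 30 did not pass (1 and 9 within the list) at day 5. Of 14 brown adipocyte and thermogenic genes, 1 rose, 0 fell and 13 did not pass (1 and 5 within the list) at day 5, beside a median of 0.049 for the skeletal muscle genes. Of 28 lymphocyte and lymph node genes, 0 rose, 0 fell and 28 did not pass (0 and 0 within the list) at day 5.

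In all, 270 genes passed at day 2, 206 higher and 64 lower, and 372 at day 5, 224 higher and 148 lower. With the experiment as a block the counts were 473 and 777. Without either pool of day 7 they were 64 and 152, without either of day 14 69 and 103, and without either of day 28 49 and 94. They were 95 and 128 from the deposited log ratio, 42 and 74 from arrays with estradiol in Cy5, and 132 and 133 from those with it in Cy3. Camera moved 7 lists up and 2 down at day 2, and 8 up and 5 down at day 5. With an estimated correlation it called 0 at either day (smallest adjusted p = 0.0619 and 0.144). The day 2 call of milk protein genes was lost without either day 28 pool (adjusted p = 0.0636) and with the experiment as a block (0.0604). It was also lost with median centring (0.0501) and from arrays with estradiol in Cy5 (0.436). The block newly called thermogenic (adjusted p = 0.0273), fatty acid oxidation (0.0273) and skeletal muscle genes (7.53e-08) at day 2. At day 5 it called antigen presentation (0.0268) and skeletal muscle genes (3.18e-06). Days 2 and 5 lack WK1-placebo pools, so the block's values and counts there carry part of the difference between placebos on later days. Its muscle medians were -0.90 and -0.63, against -0.048 and 0.049 without it. From arrays with estradiol in Cy5 the day 5 calls of endothelial (adjusted p = 0.120), immediate early (0.181) and milk protein genes (0.111) were lost.

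**Figure D1:**
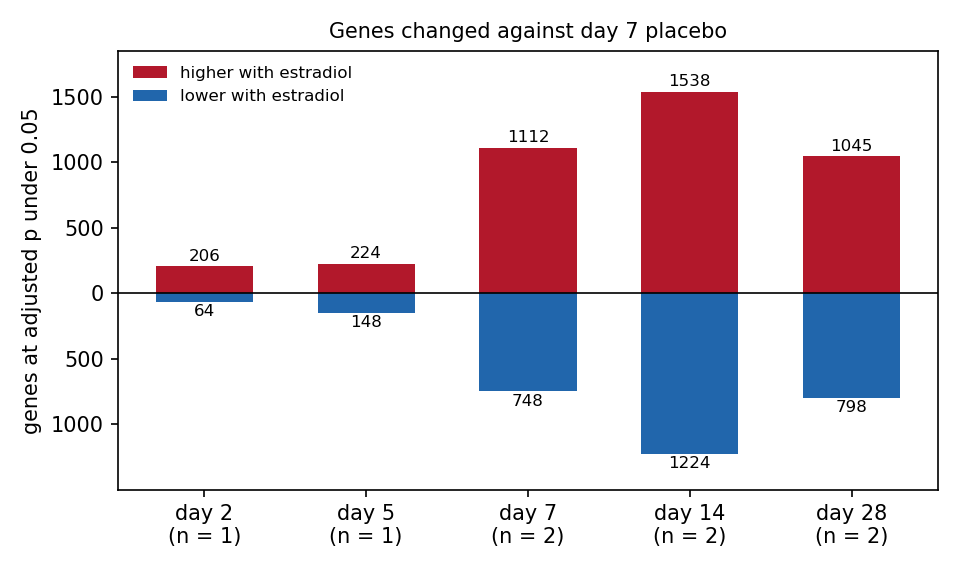
Number of genes at adjusted p under 0.05 (vertical axis, genes) at each day of estradiol (horizontal axis, with n pools), higher above 0 and lower below 0. The bars run from 206 higher and 64 lower at day 2 to 1538 and 1224 at day 14, and days 2 and 5 rest on 1 pool each.

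**Figure D2:**
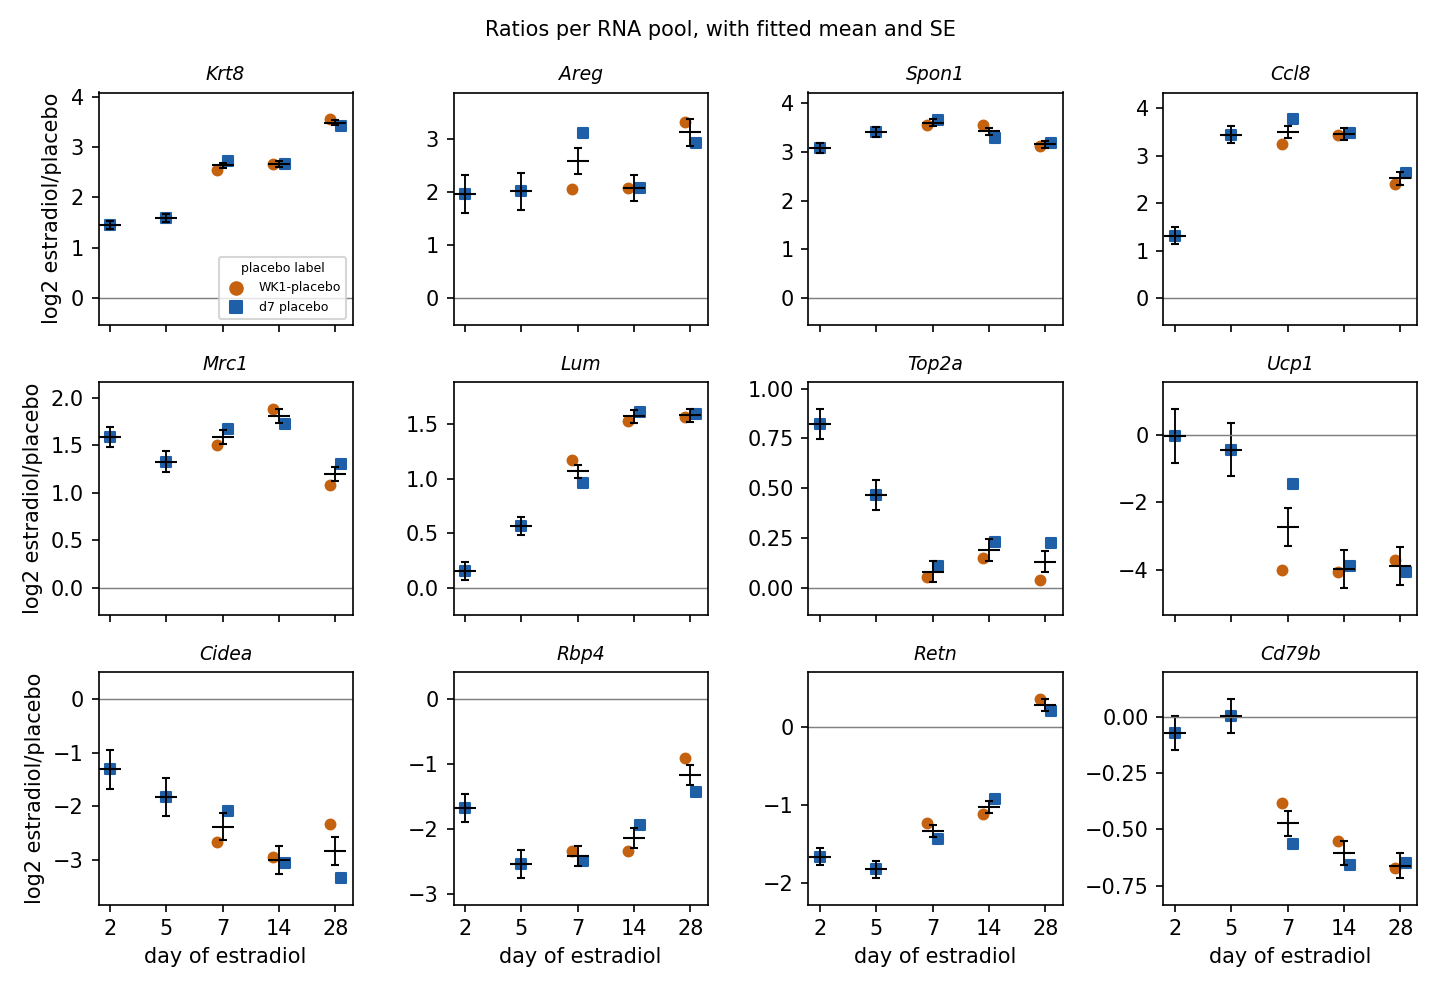
Log2 ratio of estradiol over placebo (vertical axes) of 12 genes at each day (horizontal axes), with 1 point per RNA pool coloured by its placebo label and a bar for the fitted mean ± SE. Krt8 was 1.46 at day 2 and 3.48 at day 28, Top2a 0.82 and 0.13, and Ucp1 -0.033 and -3.88.

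The mean over days 7, 14 and 28 (n = 6 ratios that share a placebo label within an experiment) gives the average response of the replicated days. Its SE came from the spread within days, so a gene could pass without a like response at each day. Spon1 was 10.5-fold higher (log2 3.39 ± 0.039, adjusted p = 1.70e-05) and Krt8 7.61-fold higher (log2 2.93 ± 0.033, adjusted p = 1.70e-05). Ucp1 was 11.5-fold lower (log2 -3.53 ± 0.32, adjusted p = 0.00144) and Cidea 6.66-fold lower (log2 -2.74 ± 0.15, adjusted p = 0.000336). Of 19108 genes, 5380 passed, 2815 higher and 2565 lower, and 227 of these differed at least 2-fold. With days taken as replicates, 5409 genes passed with d7 placebo alone and 2954 with WK1-placebo alone (n = 3 each). These held 4008 and 2529 of the 5380 and reversed 0, which is no test as the ratios are shared. A trait of a shared placebo pool would repeat in each ratio. A fixed block gave 6778, a random block 4296 and arrays with estradiol in Cy5 3480. Every gene named below as risen or fallen over these days had its direction in all 6 ratios, except Adipoq and Jchain with 5. Krt15 (basal list, higher) and Retn (adipocyte list, lower) passed too, but their pools differed in direction. Krt15 lay below placebo in a day 7 pool. Retn lay below placebo in each day 7 pool and above it in each day 28 pool. In limma with d7 placebo alone Krt15 had log2 0.96 (adjusted p = 0.121) and Retn -0.73 (0.148). With WK1-placebo alone they had 0.94 (0.330) and -0.67 (0.299). Camera called 17 of 22 lists, 10 up and 7 down, and fry called 18. With an estimated correlation camera called 0 (smallest adjusted p = 0.271).

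Epithelial, proliferation and secretory groups over days 7, 14 and 28 (n = 6) follow, of whose camera calls 0 held with an estimated correlation. Of 30 luminal epithelial genes, 26 rose, 0 fell and 4 did not pass (26 and 0 within the list). Krt7 (log2 1.95 ± 0.048), Krt18 (log2 2.38 ± 0.064) and Areg (log2 2.59 ± 0.14) rose. The list shifted up by camera (median log2 0.45, 0.59 with d7 placebo and 0.30 with WK1-placebo, adjusted p = 4.70e-11). Of 22 basal and myoepithelial genes, 11 rose, 1 fell and 10 did not pass (13 and 1 within the list). Oxtr (log2 1.68 ± 0.18), the oxytocin receptor, Sfn (log2 0.25 ± 0.023) and Tagln (log2 0.33 ± 0.037) rose. As a group they moved up by camera (median log2 0.26, 0.33 with d7 placebo and 0.16 with WK1-placebo, adjusted p = 0.000162). Krt14 (adjusted p = 0.0202) and Krt5 (0.0244) passed too, but not without day 14 replicate 2 (0.0624 and 0.0958). Krt14 was also lost without day 28 replicate 1 (adjusted p = 0.0647) or 2 (0.0811), and Krt5 without day 7 replicate 2 (0.0799) or day 14 replicate 1 (0.0702). With WK1-placebo alone Tagln (adjusted p = 0.113), Krt14 (0.191) and Krt5 (0.246) were lost, Krt5 also with a random block (0.0647). Of 24 estrogen receptor target and hormone signalling genes, 11 rose, 1 fell and 12 did not pass (12 and 2 within the list). Stc2, a secreted glycoprotein, was 1.87-fold higher (log2 0.90 ± 0.13). This list shifted up by camera (median log2 0.072, 0.11 with d7 placebo and 0.068 with WK1-placebo, adjusted p = 0.00843). Greb1, a coactivator of the estrogen receptor, passed (adjusted p = 0.00722). Its placebo signal was not above background at days 14 and 28, where its ratio was at least 3.54-fold and at least 1.99-fold. Esr1, the estrogen receptor, had log2 -0.013 ± 0.021, adjusted p = 0.690, Wnt4 log2 0.056 ± 0.033, adjusted p = 0.279 and Tnfsf11 log2 -0.038 ± 0.022, adjusted p = 0.260. Pgr, the progesterone receptor, had log2 0.27 ± 0.052, adjusted p = 0.0169, lost without day 7 replicate 2 (0.0610) or day 14 replicate 2 (0.0655). Myc had log2 0.23 ± 0.050, adjusted p = 0.0251, lost without day 7 replicate 2 (0.0815) or day 14 replicate 1 (0.0911) or 2 (0.0876). With WK1-placebo alone Greb1 (adjusted p = 0.0706), Pgr (0.0759) and Myc (0.0908) were lost, and from arrays with estradiol in Cy5 Pgr (0.117) and Myc (0.254).

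Of 32 mitosis genes, 20 rose, 1 fell and 11 did not pass (23 and 1 within the list). Ccnb2 (log2 0.24 ± 0.022), Cenpe (log2 0.22 ± 0.020) and Prc1 (log2 0.23 ± 0.025) rose. The mitosis genes moved up by camera (median log2 0.11, 0.16 with d7 placebo and 0.094 with WK1-placebo, adjusted p = 9.43e-08). Top2a had log2 0.14 ± 0.031, adjusted p = 0.0284, lost without each pool except day 28 replicate 1 (highest adjusted p = 0.106). It was also lost from arrays with estradiol in Cy5 (adjusted p = 0.0638) or Cy3 (0.390), with d7 placebo alone (0.116) and with WK1-placebo alone (0.210). Ccnb2 was lost with d7 placebo alone (adjusted p = 0.0585). Mki67 had log2 0.089 ± 0.041, adjusted p = 0.182, and passed with the experiment as a block (adjusted p = 0.0209). Of 29 DNA replication genes, 7 rose, 1 fell and 21 did not pass (8 and 1 within the list). Mcm6 (log2 0.22 ± 0.017) and Tk1 (log2 0.22 ± 0.025) rose. The list shifted up by camera (median log2 0.058, 0.090 with d7 placebo and 0.034 with WK1-placebo, adjusted p = 0.0225). Orc6, part of the origin recognition complex, fell (log2 -0.11 ± 0.019), but not without day 14 replicate 1 (adjusted p = 0.0514), with d7 placebo alone (adjusted p = 0.0568) or with WK1-placebo alone (adjusted p = 0.228). From arrays with estradiol in Cy3 alone Orc6 had log2 -0.00063 (adjusted p = 0.994). The list's call was lost without day 14 replicate 2 (adjusted p = 0.0717), without day 28 replicate 2 (0.0545) and with WK1-placebo alone (0.102). Of 24 milk protein and secretory genes, 9 rose, 2 fell and 13 did not pass (9 and 2 within the list). Csn3 (log2 1.18 ± 0.052), Wfdc18 (log2 2.29 ± 0.12) and Tph1 (log2 0.88 ± 0.053) rose. As a group they moved up by camera (median log2 0.053, 0.080 with d7 placebo and 0.031 with WK1-placebo, adjusted p = 0.00258). The milk protein genes Csn2 (log2 0.055 ± 0.038, adjusted p = 0.345), Wap (log2 -0.016 ± 0.017, adjusted p = 0.535) and Lalba (log2 0.016 ± 0.030, adjusted p = 0.740) did not pass. Ltf, lactoferrin, had log2 0.50 ± 0.084, adjusted p = 0.0103, lost without day 14 replicate 1 (adjusted p = 0.0506). Of 24 secretory pathway and protein folding genes, 18 rose, 0 fell and 6 did not pass (19 and 0 within the list). Kdelr3 (log2 0.95 ± 0.025) and Sec24d (log2 0.51 ± 0.038), of transport through the endoplasmic reticulum and Golgi, rose. The secretory list moved up by camera (median log2 0.30, 0.27 with d7 placebo and 0.29 with WK1-placebo, adjusted p = 6.95e-08).

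Adipocyte and energy metabolism groups over the same days (n = 6) follow, with 0 camera calls kept under an estimated correlation. Of 32 fatty acid oxidation and mitochondrial genes, 1 rose, 30 fell and 1 did not pass (1 and 30 within the list). Idh3a (log2 -1.09 ± 0.034) and Sdhb (log2 -0.68 ± 0.028) fell. The list shifted down by camera (median log2 -0.63, -0.58 with d7 placebo and -0.66 with WK1-placebo, adjusted p = 9.68e-16). The risen gene, picked out after its value was seen, was Cpt1a (log2 0.50 ± 0.041, adjusted p = 0.000999). Of 14 brown adipocyte and thermogenic genes, 1 rose, 12 fell and 1 did not pass (1 and 13 within the list). Cox7a1 (log2 -2.21 ± 0.12), Cox8b (log2 -1.57 ± 0.10) and Ppargc1a (log2 -0.43 ± 0.032) fell. These genes moved down by camera (median log2 -1.22, -0.99 with d7 placebo and -1.24 with WK1-placebo, adjusted p = 9.43e-08). The risen gene, likewise picked out afterwards, was Dio2 (log2 0.44 ± 0.044, adjusted p = 0.00188), which activates thyroid hormone. Of 22 skeletal muscle genes, 0 rose, 2 fell and 20 did not pass (0 and 2 within the list). Casq1 (log2 -0.67 ± 0.097) and Pvalb (log2 -1.75 ± 0.29) fell. Beside them the skeletal muscle list moved down by camera (median log2 -0.84, -0.11 with d7 placebo and -1.77 with WK1-placebo, adjusted p = 0.000813). The muscle call was lost with d7 placebo alone (adjusted p = 0.376), and Actn3 (log2 -1.42 ± 0.39, adjusted p = 0.0508) and Myh4 (log2 -1.66 ± 0.48, adjusted p = 0.0584) did not pass. Both passed with the experiment as a block (adjusted p = 0.00136 and 0.00533), with median centring (adjusted p = 0.0279 and 0.0419), without day 7 replicate 2 (adjusted p = 0.0213 and 0.0110) and with WK1-placebo alone (adjusted p = 0.00672 and 0.0209). Myh4 passed with d7 placebo alone too (log2 -0.68, adjusted p = 0.0247). Actn3 also passed with the strict filter, with a variance trend and from arrays of either dye orientation (highest adjusted p = 0.0485). Of 29 lipid synthesis genes, 0 rose, 21 fell and 8 did not pass (0 and 21 within the list). Dgat2 (log2 -1.09 ± 0.045), Acacb (log2 -1.34 ± 0.090) and Agpat2 (log2 -1.16 ± 0.081) fell. The lipid synthesis list moved down by camera (median log2 -0.47, -0.33 with d7 placebo and -0.57 with WK1-placebo, adjusted p = 5.93e-09). Of 28 adipocyte genes, 2 rose, 13 fell and 13 did not pass (4 and 14 within the list). Rbp4 (log2 -1.91 ± 0.087), Lpl (log2 -0.70 ± 0.050) and Plin1 (log2 -0.49 ± 0.021) fell. The adipocyte list moved down by camera (median log2 -0.25, -0.22 with d7 placebo and -0.20 with WK1-placebo, adjusted p = 0.00126). Adipoq had log2 -0.43 ± 0.085, adjusted p = 0.0182, lost without day 7 replicate 2 (adjusted p = 0.0640) or day 14 replicate 1 (adjusted p = 0.0515) or 2 (adjusted p = 0.0760) and with WK1-placebo alone (adjusted p = 0.382), and the leptin gene Lep had log2 0.036 ± 0.025, adjusted p = 0.356.

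Stromal and immune groups over the same days (n = 6) follow, again with 0 kept under an estimated correlation. Of 28 macrophage and myeloid genes, 23 rose, 0 fell and 5 did not pass (23 and 0 within the list). Cd163 (log2 1.27 ± 0.030), Mrc1 (log2 1.53 ± 0.043) and the Fc receptor gene Fcgr3 (log2 1.28 ± 0.035) rose. The list shifted up by camera (median log2 0.81, 0.74 with d7 placebo and 0.88 with WK1-placebo, adjusted p = 2.01e-14). Of 29 fibrillar collagen and matrix genes, 21 rose, 2 fell and 6 did not pass (22 and 2 within the list). Lum (log2 1.40 ± 0.033), Fbn1 (log2 1.34 ± 0.036) and Dcn (log2 1.01 ± 0.028) rose. The matrix list moved up by camera (median log2 0.56, 0.54 with d7 placebo and 0.78 with WK1-placebo, adjusted p = 1.40e-09). The fallen genes were Col4a1 (log2 -0.29 ± 0.058, adjusted p = 0.0199), a basement membrane collagen, and Fmod (log2 -0.15 ± 0.017, adjusted p = 0.00283), picked out after their values were seen. Col4a1 was lost without either day 7 pool or day 28 replicate 2 (highest adjusted p = 0.0783), with d7 placebo alone (adjusted p = 0.0764) and with WK1-placebo alone (adjusted p = 0.0875). Fmod was lost from arrays with estradiol in Cy3 (adjusted p = 0.0647). Of 26 matrix remodelling genes, 12 rose, 3 fell and 11 did not pass (14 and 3 within the list). Adamts2 (log2 1.95 ± 0.048), Mmp14 (log2 1.26 ± 0.051) and Mmp3 (log2 0.58 ± 0.036) rose. The remodelling list moved up by camera (median log2 0.14, 0.093 with d7 placebo and 0.21 with WK1-placebo, adjusted p = 0.000404). Of 28 lymphocyte and lymph node genes, 1 rose, 25 fell and 2 did not pass (1 and 25 within the list). Cd2 (log2 -0.66 ± 0.032), Cd5 (log2 -0.59 ± 0.028), Cd79b (log2 -0.58 ± 0.031) and Fcmr (log2 -0.55 ± 0.033), surface proteins of T or B cells, fell. As a group they moved down by camera (median log2 -0.46, -0.49 with d7 placebo and -0.48 with WK1-placebo, adjusted p = 4.02e-13). The risen gene, picked out after its value was seen, was Jchain (log2 0.47 ± 0.10, adjusted p = 0.0237). It was higher in 5 of 6 ratios and lost without either day 14 pool or day 28 replicate 2 (highest adjusted p = 0.0909), with d7 placebo alone (adjusted p = 0.358), with WK1-placebo alone (adjusted p = 0.0965) and with a random block (adjusted p = 0.0631). Of 22 endothelial genes, 4 rose, 12 fell and 6 did not pass (4 and 15 within the list). Icam2 (log2 -0.58 ± 0.022), Emcn (log2 -0.33 ± 0.017) and Robo4 (log2 -0.59 ± 0.038) fell. Pdpn (log2 0.83 ± 0.066) rose. The endothelial list moved down by camera (median log2 -0.21, -0.22 with d7 placebo and -0.15 with WK1-placebo, adjusted p = 0.000676).

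Camera did not call the other 5 lists over days 7, 14 and 28 (n = 6). Of 25 antigen presentation and interferon genes, 7 rose, 3 fell and 15 did not pass (9 and 3 within the list, median log2 0.096, 0.031 with d7 placebo and 0.098 with WK1-placebo, adjusted p = 0.111). Isg15 (log2 1.56 ± 0.17, adjusted p = 0.00239) and Irf7 (log2 0.93 ± 0.066, adjusted p = 0.000689), of the interferon response, rose, while Irf1 (log2 -0.26 ± 0.020, adjusted p = 0.000871) and the chemokine gene Cxcl9 (log2 -0.58 ± 0.064, adjusted p = 0.00268) fell. This list was called without day 7 replicate 2 (adjusted p = 0.0367), without day 14 replicate 2 (adjusted p = 0.00553), with WK1-placebo alone (adjusted p = 0.0251) and from arrays with estradiol in Cy3 (adjusted p = 0.0322). Of 24 immediate early and stress genes, 7 rose, 3 fell and 14 did not pass (9 and 5 within the list, median log2 0.048, 0.039 with d7 placebo and 0.042 with WK1-placebo, adjusted p = 0.106). Egr2 was 4.84-fold higher (log2 2.27 ± 0.068, adjusted p = 8.29e-05) and Jun 1.41-fold higher (log2 0.50 ± 0.021, adjusted p = 0.000224), and fry called the list (adjusted p = 0.00222). Of 34 growth factor and branching genes, 8 rose, 3 fell and 23 did not pass (9 and 4 within the list, median log2 0.0076, 0.023 with d7 placebo and -0.0034 with WK1-placebo, adjusted p = 0.341). Tgfb2 (log2 0.52 ± 0.044), Tgfb3 (log2 0.78 ± 0.070) and Egfr (log2 0.39 ± 0.038) rose, and the list was called by fry (adjusted p = 0.00804) and by camera with median centring (median log2 0.043, adjusted p = 0.0431). Of 17 nerve and Schwann cell genes, 4 rose, 3 fell and 10 did not pass (4 and 5 within the list, median log2 -0.019, -0.0038 with d7 placebo and -0.027 with WK1-placebo, adjusted p = 0.542). Sox10 (log2 0.14 ± 0.023, adjusted p = 0.0102) rose, and the myelin genes Mbp (log2 -0.96 ± 0.041) and Pmp22 (log2 -0.50 ± 0.043) fell. Sox10 was lost with WK1-placebo alone (adjusted p = 0.0911) and from arrays with estradiol in Cy5 (adjusted p = 0.0605) or Cy3 (adjusted p = 0.112). The mean of this list was 0.061, opposite in sign to its median and to camera's direction. Of 6 red blood cell genes, 0 rose, 0 fell and 6 did not pass (0 and 0 within the list, median log2 0.070, 0.014 with d7 placebo and 0.12 with WK1-placebo, adjusted p = 0.341). Alas2, of heme synthesis, had log2 0.18 ± 0.060, adjusted p = 0.0900, and passed without day 14 replicate 2 (adjusted p = 0.0404).

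**Figure D3:**
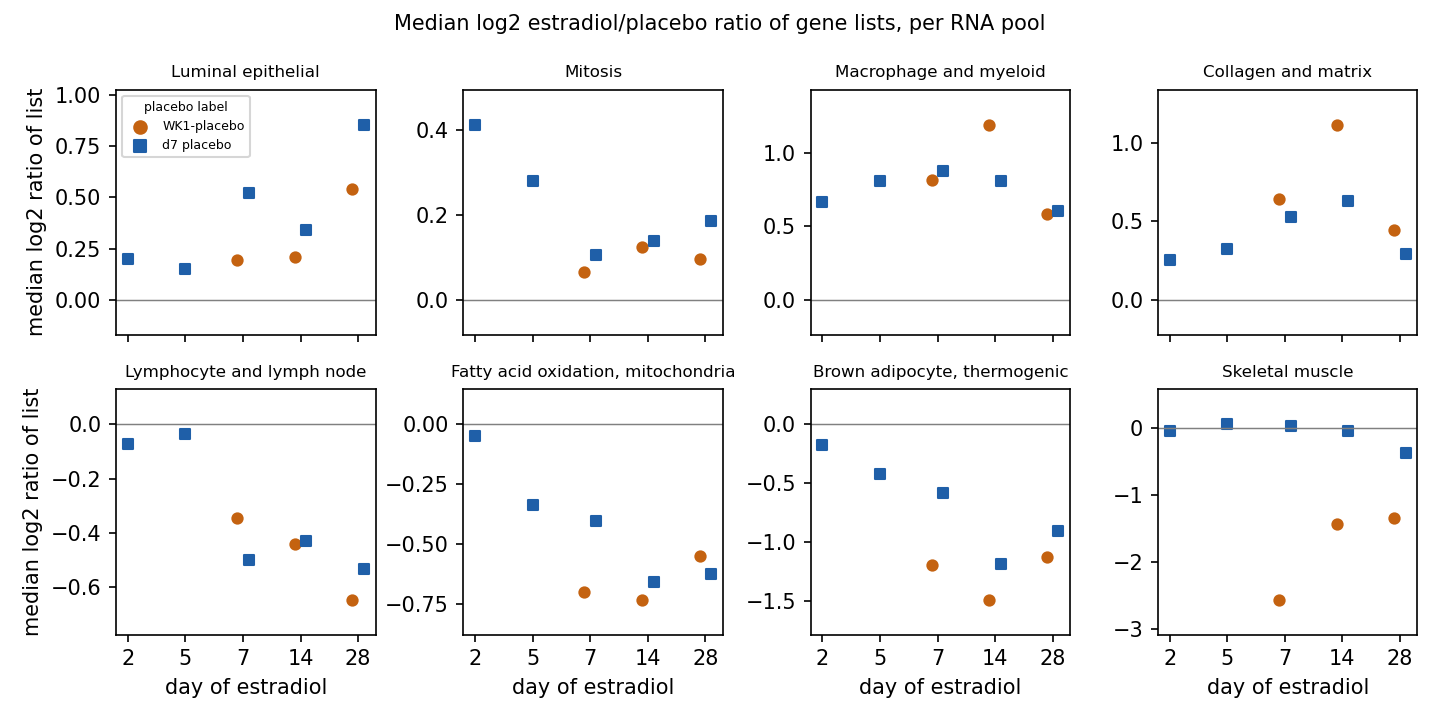
Median log2 ratio of estradiol over placebo (vertical axes) of the members of 8 gene lists in each RNA pool, by day (horizontal axes), coloured by the placebo label. Skeletal muscle genes lay at -2.56, -1.44 and -1.34 with WK1-placebo and at 0.019, -0.057 and -0.39 with d7 placebo, and macrophage and myeloid genes above 0 in all 8 pools.

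The contrast of day 28 with day 7 (n = 2 against 2) asks what changed with time under estradiol, and the placebo cancels within an experiment if its label stands for 1 RNA pool, which the labels do not state. Limma called 0 of 19108 genes (smallest adjusted p = 0.0670), with 1142 at an unadjusted p under 0.05. With the experiment as a block it called 0 (1787 unadjusted), with a random block 6, and with median centring 2. Among the larger differences, Krt15 was log2 2.32 ± 0.16, adjusted p = 0.0693, from -0.21 and 0.0067 in the day 7 pools to 2.42 and 2.02 in those of day 28. The fibrinogen gene Fgb was log2 2.07 ± 0.25, adjusted p = 0.199, and Gsta3 log2 1.91 ± 0.39, adjusted p = 0.413. Lrg1 was log2 -1.47 ± 0.16, adjusted p = 0.184, the haptoglobin gene Hp log2 -1.45 ± 0.24, adjusted p = 0.299, Prg4 log2 -1.47 ± 0.25, adjusted p = 0.299 and Nnat log2 -1.91 ± 0.36, adjusted p = 0.348. Igh-1a (log2 1.90 ± 0.71), Cyp2e1 (log2 1.85 ± 0.38) and Uts2 (log2 -1.27 ± 0.088) did not pass either. Krt15 passed with median centring (adjusted p = 0.00804) and with a random block (adjusted p = 0.0499), and Uts2 with a random block (adjusted p = 0.0393).

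By group, camera moved 6 lists up and 7 down between day 7 and day 28 (n = 2 against 2), although no member passed over all genes. Luminal epithelial genes had a median difference of 0.32 (adjusted p = 1.10e-11), with 4 of 30 passing when adjusted over the list alone. Macrophage and myeloid genes had -0.29 (adjusted p = 1.87e-10) and immediate early and stress genes -0.20 (adjusted p = 1.04e-05), and only these 3 calls held with each pool left out. Of the 13 calls the estimated correlation left 0 (smallest adjusted p = 0.290), the block ended those of the adipocyte genes (adjusted p = 0.0677) and red blood cell genes (adjusted p = 0.0510), and fry called 0 lists (smallest adjusted p = 0.104).

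The contrast of days 2 and 5 with days 7, 14 and 28 (n = 2 against 6) sets the early response against the later one. Of 19104 genes, 38 passed, 0 higher and 38 lower in the early pools. Pamr1 was 2.99-fold lower (log2 -1.58 ± 0.047, adjusted p = 0.00507). Col14a1, a collagen of connective tissue, was 2.82-fold lower (log2 -1.49 ± 0.072, adjusted p = 0.00935), Retnla 2.81-fold lower (log2 -1.49 ± 0.073, adjusted p = 0.00935), and Krt15 2.77-fold lower (log2 -1.47 ± 0.13, adjusted p = 0.0449). Fndc1 was 2.97-fold lower (log2 -1.57 ± 0.14, adjusted p = 0.0418), but its 2 probes had log2 -0.045 and 0.33 over days 7, 14 and 28. On the other side, values that did not pass were Ucp1 (log2 3.29 ± 0.65, adjusted p = 0.122), Cox7a1 (log2 1.71 ± 0.24, adjusted p = 0.0723), Cox8b (log2 1.39 ± 0.21, adjusted p = 0.0790), Pdk4 (log2 1.24 ± 0.24, adjusted p = 0.117) and Cidea (log2 1.17 ± 0.29, adjusted p = 0.181). Ucp1, Cox7a1 and Cox8b passed without day 7 replicate 1 (adjusted p = 0.0271, 0.0293 and 0.0343) and without day 7 replicate 2 (adjusted p = 0.0138, 0.0172 and 0.0237). With 1 pool fewer, 0 of the 38 passed without either day 14 pool, 1 without either day 28 pool, 12 without day 7 replicate 1 and 30 without day 7 replicate 2, where 1, 21 and 59 genes passed in all. Pamr1 was lost without either day 14 pool (adjusted p = 0.0588 and 0.0615), and Col14a1 (highest adjusted p = 0.101) and Retnla (highest adjusted p = 0.101) without each pool of days 14 and 28. Fndc1 (highest adjusted p = 0.119) and Krt15 (highest adjusted p = 0.130) were lost without each of the 6 pools. The ratios themselves moved little in these fits: log2 ran over -1.58 to -1.58 for Pamr1, -1.46 to -1.52 for Col14a1, -1.46 to -1.52 for Retnla, -1.40 to -1.53 for Krt15 and -1.49 to -1.65 for Fndc1. From arrays with estradiol in Cy5 Pamr1 (adjusted p = 0.0931), Col14a1 (adjusted p = 0.0788), Retnla (adjusted p = 0.149), Krt15 (adjusted p = 0.0585) and Fndc1 (adjusted p = 0.107) were lost. From those with it in Cy3 Retnla (adjusted p = 0.0605) and Krt15 (adjusted p = 0.0706) were lost, and from the deposited log ratio Krt15 (adjusted p = 0.0863) and Fndc1 (adjusted p = 0.0652). With the experiment as a block 228 genes passed, 42 higher and 186 lower. With a random block 195 passed, with the strict filter 60, and from the deposited log ratio 8. Within d7 placebo, which holds both early pools, 0 passed in limma with days taken as replicates (2848 unadjusted). The ratios were as large: log2 -1.61 for Pamr1, -1.49 for Col14a1, -1.51 for Retnla, -1.48 for Krt15 and -1.65 for Fndc1.

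By group, camera moved 7 lists up and 6 down in the early pools (n = 2 against 6), and 0 with an estimated correlation (smallest adjusted p = 0.104). The median difference was 0.20 for mitosis genes (adjusted p = 1.94e-20) and 0.15 for DNA replication genes (adjusted p = 4.24e-11). Adjusted over the list alone, 23 of 32 mitosis and 12 of 29 DNA replication genes were higher in the early pools. Fry called mitosis (adjusted p = 0.0111) and no other list. Lymphocyte and lymph node genes differed by 0.35 (adjusted p = 7.50e-17). Fatty acid oxidation and mitochondrial genes differed by 0.39 (adjusted p = 8.76e-19) and brown adipocyte and thermogenic genes by 0.59 (adjusted p = 5.76e-09), beside 0.97 for skeletal muscle genes (adjusted p = 0.000952). With d7 placebo alone the muscle difference was 0.15 (adjusted p = 0.243), that of the thermogenic genes 0.47 (adjusted p = 5.09e-07) and that of the fatty acid oxidation genes 0.36 (adjusted p = 1.22e-12). Luminal epithelial genes differed by -0.25 (adjusted p = 3.58e-10) and fibrillar collagen and matrix genes by -0.28 (adjusted p = 1.09e-08). With the experiment as a block the calls of the skeletal muscle genes (adjusted p = 0.559) and antigen presentation and interferon genes (adjusted p = 0.183) were lost, and the adipocyte genes (adjusted p = 0.00827) and estrogen receptor target and hormone signalling genes (adjusted p = 0.00857) were newly called.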

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

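The 10 tests of explanations in this part were chosen only after the results were seen, as were the fits of each experiment alone. The criteria were changed more than once after values were seen. Those between 2 lists first asked only for a permutation p, then also for a difference beyond the SD over either list, and now beyond the SD over the genes that the explanation needs to move. Those against the same placebo label now also ask for the SD between pools, and those of day 7, at first a count, for a median beyond the SD over members. The readings that depend on this are named below. The permutations took genes as independent, but the estimated correlation was 0.865 for muscle and 0.24 for thermogenic genes. Their p values are thus likely too small, and the SD over members is no error of a median. The labels name no sorting or gating of cells, so each pool holds the RNA of the whole gland. The 3 lists weighed share no gene with the other lists among the abundant members quoted.

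Lymphocyte and lymph node genes were lower over days 7, 14 and 28 (25 of 28, median log2 -0.46) and differed between the early and later days by 0.35 (camera adjusted p = 7.50e-17, adjusted p = 0.240 with an estimated correlation), and Coro1a (mean log2 signal 12.8) had log2 -0.37 with WK1-placebo, -0.46 with d7 placebo and -0.020 at days 2 and 5, and Cd79b (mean log2 signal 12.1) had log2 -0.54 with WK1-placebo, -0.62 with d7 placebo and -0.033 at days 2 and 5. Lymph node RNA in the placebo pool as the whole cause would lower days 2 and 5 alike if the label stands for 1 RNA pool, which the labels do not state, but against the same placebo label B cell genes differed by 0.44 (SD over members 0.13; pool medians 0.44, SD between pools 0.077) and T cell genes by 0.27 (0.12; 0.32, 0.078). Dilution by RNA of the growing gland would lower endothelial genes as much. Their median was -0.21, and the lymphocyte median differed from it by -0.25 (2-sided permutation p = 0.00698, 28 against 22 genes). This lies within the SD over the endothelial genes of 0.40 (lymphocyte genes 0.27), so dilution and the other open explanations cannot be told apart, while the permutation alone would have argued against dilution. A part of the T cell difference may still come from the placebo pool, since T cell genes were -0.32 at day 2 and -0.22 at day 5, against 0.026 and 0.091 for B cell genes. A lower share of lymph node in the later estradiol glands and an effect of estradiol on lymphocytes stay open. The lack of a time-matched placebo at days 14 and 28 as the whole cause is argued against by day 7, whose placebo was matched and where 17 of 28 genes fell (median -0.43, SD over members 0.19).

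Skeletal muscle genes differed by 0.97 between the early and later days (camera adjusted p = 0.000952, adjusted p = 0.598 with an estimated correlation), but by 0.15 with d7 placebo alone: Tnnc2 (mean log2 signal 13.7) had log2 -2.21 with WK1-placebo, -0.089 with d7 placebo and -0.038 at days 2 and 5, and Myh4 (mean log2 signal 13.4) had log2 -2.65 with WK1-placebo, -0.68 with d7 placebo and -0.26 at days 2 and 5. The ratio cannot show which channel differed. Relative to the median of each array, the muscle signal of the placebo channel was 1.25 higher with WK1-placebo than with d7 placebo (member median, SD over members 0.84), and that of the estradiol channel differed by -0.41 (SD over members 0.48). An effect of estradiol on the muscle genes of the gland would lower both experiments alike, but with d7 placebo the member median was -0.11, against -1.77 with WK1-placebo (SD over members 0.79 with d7 placebo and 1.099 for the difference). This argues against it as the whole cause, while Myh4 was lower with d7 placebo alone too (adjusted p = 0.0247), so a smaller effect on single muscle genes stays open. Muscle beside the placebo glands labelled WK1-placebo is a candidate explanation, resting on 1 placebo label per experiment, and what else differed between the experiments stays open.

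Brown adipocyte and thermogenic genes were lower over days 7, 14 and 28 (12 of 14) and differed between the early and later days by 0.59 (camera adjusted p = 5.76e-09, adjusted p = 0.240 with an estimated correlation), and Cidea (mean log2 signal 13.6) had log2 -2.65 with WK1-placebo, -2.83 with d7 placebo and -1.57 at days 2 and 5, and Cox8b (mean log2 signal 12.9) had log2 -1.66 with WK1-placebo, -1.48 with d7 placebo and -0.18 at days 2 and 5. A lower share of adipocyte RNA as the whole cause would lower adipocyte genes as much, but the thermogenic median differed from theirs by -0.97 (2-sided permutation p = 0.000140, 14 against 28 genes), beyond the SD over the adipocyte genes of 0.50 but within that over the thermogenic genes of 1.08. Muscle RNA in the placebo pool would lower muscle genes as much, but in the d7 placebo pools the thermogenic median differed from theirs by -0.89 (2-sided permutation p = 8.00e-05, SD over the muscle genes 0.79, thermogenic genes 1.03). Both are thus only weakly argued against as the whole cause, by the SD over the genes that would need to move. With the SD over the thermogenic genes neither could be told apart from the rest. Brown fat RNA in the placebo pool, the lack of a time-matched placebo at days 14 and 28 and an effect of estradiol cannot be told apart. Against the same placebo label days 2 and 5 differed from the later days by 0.47, within the SD over members of 0.78 (pool medians 0.59, SD between pools 0.27). At day 7, whose placebo was matched, 9 of 14 genes fell (median -0.90, SD over members 0.90, not beyond it), with pool medians of -1.19 and -0.58.

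Other lists differed between day 28 and day 7 by camera (n = 2 against 2 pools), and 0 of these calls held with an estimated correlation (smallest adjusted p = 0.290) or by fry. The median differences were 0.32 for luminal epithelial genes (adjusted p = 1.10e-11), -0.29 for macrophage and myeloid genes (adjusted p = 1.87e-10) and -0.20 for immediate early and stress genes (adjusted p = 1.04e-05), and these calls held with each pool left out. Those of 0.0025 for estrogen receptor target and hormone signalling genes (adjusted p = 0.0203), 0.037 for mitosis genes (adjusted p = 0.00306), 0.16 for basal and myoepithelial genes (adjusted p = 9.13e-05), 0.089 for lipid synthesis genes (adjusted p = 0.00902), -0.16 for lymphocyte and lymph node genes (adjusted p = 8.90e-06), -0.095 for antigen presentation and interferon genes (adjusted p = 0.0344) and -0.40 for red blood cell genes (adjusted p = 0.0215) were lost without day 7 replicate 1 (adjusted p = 0.187, 0.0564, 0.0564, 0.301, 0.0564, 0.998 and 0.187). Without day 28 replicate 2 the calls of the estrogen receptor target (adjusted p = 0.420), mitosis (0.157), antigen presentation (0.128) and red blood cell genes (0.109) were lost, as were those of -0.13 for endothelial genes (adjusted p = 0.00234, 0.157 without it) and -0.089 for brown adipocyte and thermogenic genes (adjusted p = 0.00902, 0.422 without it). Without day 28 replicate 1 they were lost for antigen presentation (0.156), red blood cell (0.168) and lipid synthesis genes (0.207), and for adipocyte genes (0.597), whose difference was 0.11 (camera adjusted p = 0.0203). Without day 7 replicate 2 they were lost for adipocyte (0.0597) and thermogenic genes (0.142).

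Between the early and later days (n = 2 against 6 pools), 38 genes differed in limma, of which Pamr1 (log2 -1.58), Fndc1 (-1.57), Col14a1 (-1.49), Retnla (-1.49) and Krt15 (-1.47) were the lowest in the early pools. With 1 pool of days 7, 14 or 28 left out at most 30 of them passed, without day 7 replicate 2, and 0 without either day 14 pool. None passed in limma with d7 placebo alone (2848 at an unadjusted p under 0.05), but with fewer pools the 5 ratios were as large (-1.48 to -1.65). By camera lists differed, 0 of them with an estimated correlation and only mitosis by fry. The differences were 0.15 for DNA replication (adjusted p = 4.24e-11), 0.20 for mitosis (1.94e-20) and -0.25 for luminal epithelial genes (3.58e-10). They were 0.39 for fatty acid oxidation (8.76e-19), -0.28 for fibrillar collagen (1.09e-08) and -0.12 for matrix remodelling genes (0.00151). These calls held with each pool left out. Those of -0.070 for basal (adjusted p = 0.0342), 0.090 for endothelial (0.0382), -0.12 for antigen presentation (0.00649) and -0.022 for growth factor genes (0.0324) did not hold. The basal and endothelial calls were lost without day 7 replicate 2 (adjusted p = 0.147 and 0.0748), day 14 replicate 2 (0.0893 and 0.110) or day 28 replicate 2 (0.0539 and 0.157). That of the growth factor genes was lost without day 7 replicate 2 (0.0784) and that of the antigen presentation genes without day 14 replicate 1 (0.0677).

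Some named genes lay above placebo in every pool of one period and below it in every pool of the other, and the limma difference did not pass. Between day 7 and day 28 these were Retn (log2 1.62, adjusted p = 0.0693), Fgb (log2 2.07, adjusted p = 0.199), Gsta3 (log2 1.91, adjusted p = 0.413), Cyp2e1 (log2 1.85, adjusted p = 0.426), Nnat (log2 -1.91, adjusted p = 0.348), Fndc1 (log2 1.79, adjusted p = 0.149), Hbb-b2 (log2 -0.96, adjusted p = 0.468), Wnt4 (log2 0.29, adjusted p = 0.611) and Wap (log2 0.086, adjusted p = 0.945). Between the early and later days they were Mmp3 (log2 -0.69, adjusted p = 0.0543) and Krt5 (log2 -0.48, adjusted p = 0.343).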

How the results depend on the processing

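The fits of each experiment alone were chosen after seeing the data, and the other alternatives were set earlier. Of 3586 results of gene lists under alternatives, 3214 kept their side of the threshold, 280 no longer passed, 83 newly passed, 7 moved and 2 reversed. Of 3856 for named genes these were 3626, 194, 24, 12 and 0. The cause was not tested except where fewer arrays or pools are named. Counts within 1.5 times the reported one are left out here. Camera's 17 list calls over days 7, 14 and 28 became 0 with an estimated correlation. Fry asks whether members differ from 0, not from other genes, and called 18 there. At days 2, 5, 7, 14 and 28 it called 3, 3, 12, 14 and 15 (camera 9, 13, 19, 16 and 17). Median centring gave 2 genes between day 28 and day 7 and turned the difference of adipocyte genes there to -0.017. It lost the call of lipid synthesis genes there (log2 0.095, adjusted p = 0.0615). It newly called fatty acid oxidation (log2 -0.20, adjusted p = 5.05e-08, -0.057 before), secretory pathway (-0.14, 0.00136), fibrillar collagen (-0.11, 0.0153) and growth factor genes (0.090, 0.0153). The deposited log ratio and the value table gave 95 genes at day 2, 128 at day 5 and 8 between early and later days, where the strict filter gave 60. The experiment as a fixed block gave 473, 777, 3313, 4250 and 3412 genes at days 2, 5, 7, 14 and 28, and 228 between early and later days. As a random block it gave 6 between day 28 and day 7 and 195 between early and later days. With 8 of the 16 arrays, estradiol in Cy5 gave 42, 74, 1024, 1255 and 921 genes at these days, 3480 over days 7, 14 and 28 and 0 between early and later days (1669 at an unadjusted p under 0.05 in limma), and estradiol in Cy3 gave 132, 133 and 1209 at days 2, 5 and 7 and 12 between early and later days. With d7 placebo alone 0 genes differed between early and later days in limma (2848 unadjusted), and with WK1-placebo alone 2954 passed over days 7, 14 and 28. With 1 pool fewer, the lone pool of a day being assumed to vary like the others, the counts ran over 49 to 69 at day 2, 94 to 152 at day 5, 391 to 1357 at day 7, 532 to 2437 at day 14, 189 to 1547 at day 28, 3668 to 4475 over days 7, 14 and 28 and 0 to 59 between early and later days. Between day 28 and day 7 they stayed at 0 in limma (1142 unadjusted with all pools), and antigen presentation genes ran from -0.1983 to -0.02799 there, with camera's direction reversed at the latter. Blocks by scan date or slide were not run, since each array is a slide of its own and the files give a scan date, a shared one, only for the d7 placebo arrays, the same split as the experiment. The lower signal of the arrays with WK1-placebo, with as few as 84.1% of spots well above background, limits ratios of dim genes. The placebo of Greb1 was not above background at days 2, 5, 14 and 28, on arrays of either placebo label.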
